A study of Homo sapiens with 6 samples.

How the data were processed

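RNA from PC-3 cells was measured on 6 Affymetrix whole-transcript arrays, 3 from cells given menthol in ethanol and 3 from cells given ethanol alone. Per the labels, the ethanol concentration was 0.1%, the medium held 10% fetal bovine serum, and 300 ng of total RNA was labelled for each array. The menthol dose, the treatment time and the summarisation software are not given in the sources used here. The authors deposited 1 table of intensity values, with 32321 probesets in each array, and the submitters' processing notes name RMA, a method of background correction, quantile normalization and probeset summary. RMA usually gives log2 values, but the deposited intensity values ranged from 1.57 to 14835 and were therefore on a linear scale, so log2 was taken first. The array medians lay between 47.4 and 49.1 intensity units. The number of arrays limits the precision.

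Probesets were named from the platform's annotation. Of the probesets, 19158 had 1 gene symbol, 1388 had several and 11775 had no gene named here. Of the Entrez identifiers of the single-symbol probesets, 19128 were found in a gene table of assembly GRCh38.p14, and 0 symbols needed updating. For each gene the probeset with the highest mean over the 6 arrays was kept, which left 18404 genes. 637 genes had more than 1 probeset.

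The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 intensity, with group as the single term), two-sided, with Benjamini-Hochberg adjustment over the 18404 genes and a threshold of 0.05. A second count added a change of at least 1.5-fold. Fold changes are menthol minus vehicle on the log2 scale, given with the moderated standard error (SE). The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. An exact permutation test of 3 against 3 arrays cannot go below 0.10.

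Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists, each with at least 5 measured members. The lists held 1015 memberships, of which 917 were measured. The lists, the design, the tests, the alternatives and the rule for named genes were set before the data were examined. By that rule the text names the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap, passing over small RNAs, unnamed transcripts and receptor segments. It also names members of each list from among the up to 4 with the largest change past the threshold, or up to 2 with the smallest p where none passed, and TRPM8 and TRPA1 whatever their values. The rule passed over 2 small RNAs among the increases and 0 genes among the decreases. Genes named outside the rule are said to have been chosen after their values were seen.

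The fit was tested on simulated data with independent normal noise at each gene's moderated SD. In these, 200 of 18404 genes were changed in the comparison of menthol with vehicle. It recovered 94.5% of genes changed 1.5-fold with 11 false calls, and 99.5% of genes changed 2-fold with 9 false calls. The simulation held no correlation between genes and no intensity-dependent shift, so it does not give the error rate of the calls on the real arrays. The alternatives were quantile normalization, equal array medians, filters on dim genes, other uses of the probesets, an intensity-trended robust prior (statmod 1.5.0), array weights, the replicate number as a block, a threshold of 0.01, other gene list tests and the omission of each array in turn. Cyclic loess normalization was added after seeing the data. Random gene lists, permutation tests and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.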

Results

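Gene expression was measured in PC-3 cells, an androgen-independent line derived from a human prostate carcinoma. The question was how menthol, the cooling compound of mint and an agonist of the cold-sensing channel TRPM8, affects the expression profile of these cells. The vehicle group and the menthol group held 3 arrays each. The median SD between replicates was 0.08 on the log2 scale in the vehicle group and 0.10 in the menthol group. The first principal component carried 66.7% of the variance and placed the vehicle arrays between -22.65 and -19.82 and the menthol arrays between 19.64 and 22.26.

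The hair keratin gene KRT34 showed the largest increase with menthol, by 3.30 ± 0.14 (SE, n = 3 per group) on the log2 scale, or 9.87-fold. NRK, a serine/threonine kinase, rose by 2.62 ± 0.07, and the ectonucleotidase ENTPD3 by 2.54 ± 0.08. The long non-coding RNA UCA1 rose by 2.36 ± 0.17 and MACC1, a regulator of MET expression, by 2.09 ± 0.08. The genes of both ligands of the T-cell receptor PD-1 rose, PDCD1LG2 by 2.03 ± 0.13 and CD274 by 1.94 ± 0.09. The peptidase gene MME rose by 1.94 ± 0.09, and DAW1, NLRP10, MAL and RGS7BP rose by 1.90, 1.85, 1.77 and 1.74. Among these 12 genes the highest adjusted p in limma was 0.00012, that of UCA1.

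The largest decrease was that of DHRS9, a dehydrogenase acting on retinol and steroids, which fell by 2.61 ± 0.09 on the log2 scale. GABRA3, a subunit of the GABA-A receptor, fell by 2.49 ± 0.13 and the R-spondin receptor LGR5 by 2.44 ± 0.09. SERPINB4 fell by 2.34 ± 0.22, and SERPINB3, chosen after its values were seen, was 3.03-fold lower. These protease inhibitor genes are near-identical, so their separate values are uncertain. The lysyl oxidase family gene LOXL4 fell by 2.30 ± 0.07 and the growth factor receptor PDGFRA by 1.99 ± 0.14. The urea transporter SLC14A1 fell by 1.94 ± 0.13, FEZ1 by 1.84 ± 0.11, the laminin chain LAMA4 by 1.82 ± 0.08 and the phosphodiesterase PDE10A by 1.80 ± 0.08. IDO1, which starts tryptophan breakdown, fell by 1.77 ± 0.07, and SCUBE3, a secreted glycoprotein, was 3.99-fold lower with menthol. The highest adjusted p among the 12 genes of the rule was 0.00034, that of SERPINB4.

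**Figure D1:**
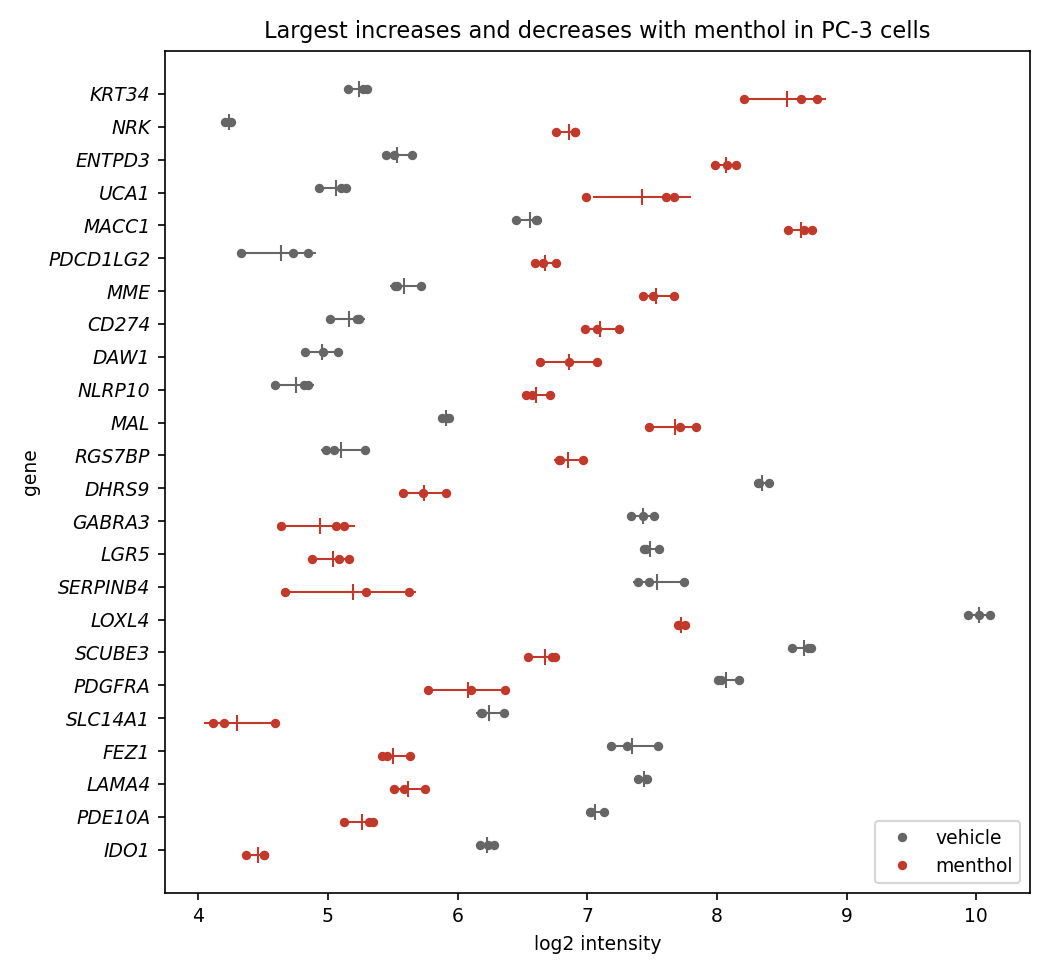
Log2 intensity (horizontal axis) of the 12 genes with the largest increase and the 12 with the largest decrease; points are single arrays, ticks are group means and bars are SD, n = 3 arrays per group. For each gene the menthol arrays lie apart from the vehicle arrays, as for KRT34 with means of 5.24 in vehicle and 8.54 in menthol.

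In all, 5353 of 18404 genes (29.1%) passed the threshold, 2683 higher and 2670 lower with menthol. Of these, 1032 had changed at least 1.5-fold, 550 higher and 482 lower, and the median change of the genes past the threshold was 1.30-fold. In 8329 genes (45.3%) the groups did not overlap, against 10% by chance. The median log2 fold change was 0.10 in the dimmest 4601 genes and -0.05 in the brightest 4601. Of the dimmest, 473 were higher and 88 lower past the threshold, and of the brightest, 792 were higher and 1239 lower.

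Of the 36 gene lists, 12 passed the threshold in camera, 9 lower and 3 higher. With an estimated correlation camera called 0 lists, with 1 list at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way, called 25. Splits of the 6 arrays that mix the groups gave up to 11 lists in camera. Such splits keep part of the difference between the groups, so this is not a count expected by chance.

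Genes of G2/M and mitosis were lower: 36 of 39 fell and 0 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.51 (camera adjusted p = 3.13e-19; adjusted p = 0.372 with an estimated correlation). HMMR, a spindle-associated protein, fell by 1.02 ± 0.09, the mitotic kinase PLK1 by 1.01 ± 0.06, the kinetochore gene SPC25 by 0.89 ± 0.08 and the cyclin CCNB2 by 0.85 ± 0.08. In the list of G1/S and DNA replication 8 of 39 genes rose and 10 fell, the same counts as adjusted over the list alone, and the list did not pass (adjusted p = 0.863, median 0.02, mean 0.01, camera direction down). The cyclin CCNE2 rose by 0.87 ± 0.08 and the replication licensing gene CDC6 by 0.48 ± 0.07. CCNA2 changed by -0.47 ± 0.07 and TYMS by -0.44 ± 0.06. Without vehicle replicate 1, 2 or 3 or menthol replicate 2, 5 genes of the G1/S list fell in place of 10. Of 26 replication-dependent histone genes 7 rose and 1 fell, as adjusted over the list alone, and the list did not pass (adjusted p = 0.0781; adjusted p = 0.697 with an estimated correlation). The histone list passed with either filter on dim genes, with the trended prior, under cyclic loess normalization and without vehicle replicate 3 (adjusted p = 0.0441) or menthol replicate 2 (adjusted p = 0.00775), in a range of 0.00724 to 0.446 over its camera alternatives at the preset correlation. H4C8 rose by 1.44 ± 0.08 and H2BC21 by 1.28 ± 0.10.

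Genes of cholesterol synthesis and uptake were higher: 14 of 21 rose and 0 fell, and 18 rose adjusted over the list alone, with a median of 0.41 (camera adjusted p = 2.07e-07; adjusted p = 0.372 with an estimated correlation). ACAT2 rose by 1.07 ± 0.09, the sterol carrier STARD4 by 1.04 ± 0.10, the lanosterol demethylase CYP51A1 by 0.97 ± 0.06 and INSIG1, a sterol-regulated brake on SREBP processing, by 0.71 ± 0.06. Of 9 genes of cholesterol efflux and LXR targets 5 fell and 1 rose, as adjusted over the list alone, and the list did not pass (adjusted p = 0.0728), except without vehicle replicate 2 (adjusted p = 0.0393, in a range up to 0.22 over its camera alternatives at the preset correlation; adjusted p = 0.372 with an estimated correlation). The sterol exporter ABCA1 fell by 1.04 ± 0.07 and ABCG1 by 0.52 ± 0.11. In fatty acid synthesis and desaturation 6 of 21 rose and 6 fell, as adjusted over the list alone (adjusted p = 0.863): the elongase ELOVL7 rose by 1.43 ± 0.07 and LPIN1 by 0.82 ± 0.06. The desaturase SCD changed by -0.83 ± 0.07 and the synthase FASN by -0.65 ± 0.06.

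Hypoxia response genes were lower, with 16 of 25 down and 2 up, the same as adjusted over the list alone, and a median of -0.32 (camera adjusted p = 1.38e-05; adjusted p = 0.393 with an estimated correlation). The collagen cross-linking enzyme LOX fell by 1.28 ± 0.10, the glycolytic regulator PFKFB3 by 1.13 ± 0.07 and the carbonic anhydrase CA12 by 0.92 ± 0.07. With each array left out in turn, 13 to 14 hypoxia response genes fell and 1 to 2 rose. Of 17 glycolysis genes 13 fell and 0 rose, and adjusted over the list alone 14 fell and 1 rose (median -0.35, camera adjusted p = 8.59e-07; adjusted p = 0.372 with an estimated correlation). The enolase ENO2 fell by 1.04 ± 0.10, ALDOC by 0.65 ± 0.07 and TPI1 by 0.60 ± 0.06. In oxidative phosphorylation 7 of 31 genes fell and 0 rose, as adjusted over the list alone (median -0.12, camera adjusted p = 0.0135; adjusted p = 0.583 with an estimated correlation). COX7B fell by 0.70 ± 0.16 and NDUFB5 by 0.43 ± 0.06. Of the brightest 4601 genes 1239 fell and 792 rose. The share that fell in this list was thus no larger than among bright genes, while 0 of its genes rose. The call on oxidative phosphorylation ended under quantile normalization, cyclic loess normalization, either filter on dim genes and without vehicle replicate 3.

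Of 34 ribosomal protein genes 14 fell and 0 rose, and 16 fell adjusted over the list alone (median -0.18, camera adjusted p = 1.38e-05; adjusted p = 0.521 with an estimated correlation). RPS3 fell by 0.64 ± 0.06 and RPS24 by 0.56 ± 0.09. Of 29 ribosome biogenesis genes 14 fell and 2 rose, and 15 fell and 2 rose adjusted over the list alone (median -0.18, camera adjusted p = 0.00051; adjusted p = 0.372 with an estimated correlation). RRP12 fell by 0.82 ± 0.07 and the rRNA methyltransferase FBL by 0.74 ± 0.07. Without vehicle replicate 3 or menthol replicate 2, 8 ribosomal protein genes fell, and without vehicle replicate 2 or menthol replicate 3, 9 fell. Without vehicle replicate 1, 9 ribosome biogenesis genes fell. With each array left out in turn, 0 to 1 of the ribosome biogenesis genes rose in place of 2.

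The list of epithelial-mesenchymal transition was higher, with 16 of 29 genes up and 5 down, and 19 up and 5 down adjusted over the list alone (median 0.28, camera adjusted p = 0.00055; adjusted p = 0.372 with an estimated correlation). Most of the members that rose are epithelial: 12 of 15 epithelial members rose and 0 fell, a division made after the values were seen, while of the 14 mesenchymal members and regulators 4 rose and 5 fell. The keratins KRT19 and KRT18 rose by 0.97 ± 0.07 and 0.87 ± 0.06, the tight junction gene CLDN7 by 0.88 ± 0.06 and ID1, an inhibitor of basic helix-loop-helix factors, by 1.09 ± 0.07. Of genes chosen after their values were seen, the adhesion molecules CDH1 and EPCAM rose by 0.78 ± 0.07 and 0.69 ± 0.08, KRT8 rose by 0.56 ± 0.06 and the mesenchymal filament gene VIM fell by 0.42 ± 0.07.

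Genes of extracellular matrix and proteases were lower on balance, with 16 of 37 down and 7 up, and 18 down and 7 up adjusted over the list alone (median -0.18, camera adjusted p = 0.00141; adjusted p = 0.372 with an estimated correlation). COL4A1 fell by 1.24 ± 0.06 and TGFBI by 1.22 ± 0.08. The protease MMP3 rose by 1.22 ± 0.08. In the list of NF-kappaB targets and inflammatory cytokines 15 of 37 fell and 5 rose, as adjusted over the list alone (median -0.14, camera adjusted p = 0.00945; adjusted p = 0.521 with an estimated correlation). The prostaglandin synthase PTGS2 changed by -1.47 ± 0.10 and IL1A by -1.29 ± 0.14. IL1RN, the antagonist of the IL-1 receptor, rose by 1.34 ± 0.08 and IL6 by 1.33 ± 0.10. The call on NF-kappaB targets ended with the stricter filter on dim genes, and without vehicle replicate 1 or menthol replicate 2, 2 of its genes rose in place of 5. Without vehicle replicate 2, 3 of them rose. Under cyclic loess normalization the median of the NF-kappaB list was -0.09 (camera adjusted p = 0.0418).

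Of 33 genes of autophagy and lysosome 12 rose and 1 fell, as adjusted over the list alone (median 0.13, camera adjusted p = 0.00071; adjusted p = 0.372 with an estimated correlation). The autophagosome gene WIPI1 rose by 1.15 ± 0.08 and GABARAPL1 by 0.57 ± 0.07. With each array left out in turn, 11 to 12 autophagy and lysosome genes rose and 0 to 1 fell. In the list of ATF4 and amino acid response 12 of 34 fell and 4 rose, and 16 fell and 4 rose adjusted over the list alone (median -0.14, camera adjusted p = 0.0142; adjusted p = 0.372 with an estimated correlation). VLDLR fell by 1.16 ± 0.09, the mTORC1 inhibitor DDIT4 by 1.07 ± 0.07 and CTH by 0.79 ± 0.06. The ATF4 call ended under quantile and cyclic loess normalization, under both filters on dim genes and without vehicle replicate 3, and without vehicle replicate 1, 2 or 3, 7 of its genes fell.

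**Figure D2:**
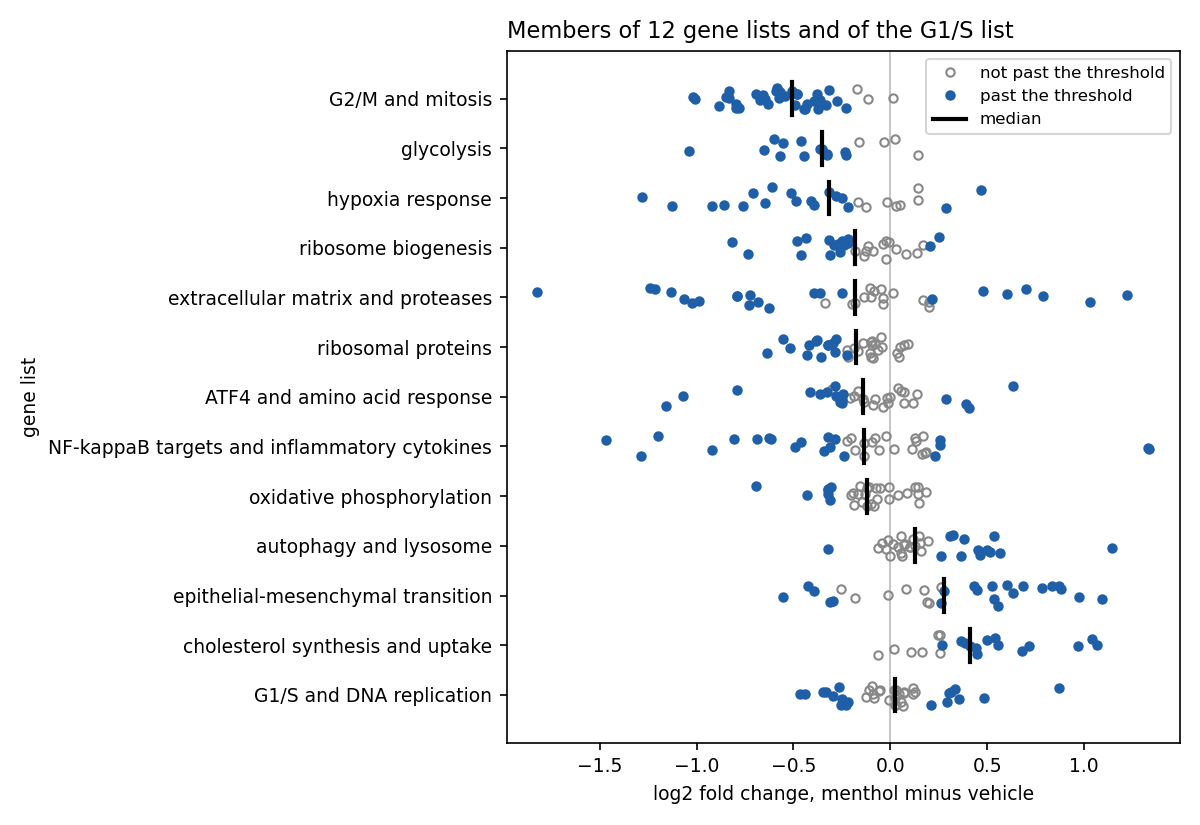
Log2 fold change, menthol minus vehicle (horizontal axis), of each measured member of the 12 gene lists that passed in camera and of the G1/S list; filled points passed the threshold over all genes, open points did not, and bars are medians. The members of the G2/M list lie mostly to the left, with a median of -0.51, and those of cholesterol synthesis and uptake mostly to the right, with a median of 0.41.

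TRPM8 itself had a low signal, 3.27 ± 0.05 (SD, n = 3) on the log2 scale with vehicle and 3.34 ± 0.26 with menthol, at the 8.25th percentile of genes, and did not pass the threshold (log2 fold change 0.08 ± 0.12, adjusted p = 0.688). TRPA1, another menthol-responsive channel, lay at the 1.51st percentile and did not pass (0.20 ± 0.10, adjusted p = 0.161). Of the 18 measured TRP channels and reported menthol targets 1 passed, adjusted over the list alone as well: the sodium channel SCN9A rose by 0.66 ± 0.07. SCN9A was dim too, at the 20.8th percentile, and of the dimmest 4601 genes 473 rose and 88 fell with menthol.

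Several further stress and signalling lists did not pass in camera. Of 25 genes of the unfolded protein response 9 rose and 2 fell, and 9 rose and 3 fell adjusted over the list alone (adjusted p = 0.562), with the chaperone gene DNAJB9 at 0.47 ± 0.08 and EDEM1 at -0.48 ± 0.07. Without vehicle replicate 1, 3 of these genes rose, without vehicle replicate 2, 4, and without menthol replicate 2, 5. Of 26 NRF2 targets 7 rose and 6 fell, and 7 rose and 8 fell adjusted over the list alone (adjusted p = 0.982), with HMOX1, which degrades heme, at 0.65 ± 0.06, NQO1 at 0.64 ± 0.07 and ABCC2 at -0.52 ± 0.06. Without vehicle replicate 1, 4 NRF2 targets rose. Of 26 p53 target genes 6 rose and 5 fell, and 7 rose and 7 fell adjusted over the list alone (adjusted p = 0.802), with TP53I3 at 0.77 ± 0.08, TP53INP1 at 0.75 ± 0.08 and CCNG1 at -0.54 ± 0.07. Of 28 apoptosis genes 8 rose and 4 fell, and 8 rose and 5 fell adjusted over the list alone (adjusted p = 0.381), with CASP10 at -0.86 ± 0.11 and CASP4 at 0.49 ± 0.08. Among 23 calcium handling genes the IP3 receptor genes moved apart, ITPR1 at -1.03 ± 0.07 and ITPR2 at 0.66 ± 0.09, with 3 genes higher and 4 lower, as adjusted over the list alone (adjusted p = 0.703). The sign differed between median, mean and camera in 9 lists, none past the threshold: G1/S, NRF2 targets, xenobiotic metabolism, immediate early genes, focal adhesion, and the luminal, basal, neuroendocrine and fibroblast markers.

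A further 7 lists did not pass. Of 34 immediate early genes 8 rose and 7 fell, and 8 rose and 8 fell adjusted over the list alone (adjusted p = 0.982). The matricellular gene CCN1 rose by 0.87 ± 0.07 and the transcription factor gene MYC fell by 0.68 ± 0.06. Without vehicle replicate 2 or menthol replicate 2, 5 immediate early genes rose, and without vehicle replicate 2 or 3 or menthol replicate 2 or 3, 4 fell. Of 22 genes of cyclin-dependent kinase inhibitors and growth arrest 5 rose and 3 fell, as adjusted over the list alone (adjusted p = 0.966). CDKN2A fell by 0.87 ± 0.07 and GADD45B rose by 0.57 ± 0.06. In this list 2 genes rose without vehicle replicate 1 or 2 or menthol replicate 2, and 3 rose without menthol replicate 3. Of 21 heat shock genes 2 rose and 6 fell, and 3 rose and 7 fell adjusted over the list alone (adjusted p = 0.267). The chaperone genes HSPB8 and CRYAB rose by 0.96 ± 0.15 and 0.63 ± 0.08, and the co-chaperone genes CHORDC1 and FKBP4 fell by 0.48 ± 0.09 and 0.38 ± 0.07. Of 33 genes of xenobiotic metabolism 6 rose and 7 fell, and 7 rose and 7 fell adjusted over the list alone (adjusted p = 0.982). CYP1B1 rose by 0.52 ± 0.07 and CYP2B6 fell by 0.53 ± 0.16. CYP2B6 did not pass without vehicle replicate 1, 2 or 3 or menthol replicate 1 or 3, with array weights or with single probesets, and without vehicle replicate 1, 4 genes of the list fell. Of 22 genes of fatty acid oxidation and PPAR targets 2 rose and 6 fell, as adjusted over the list alone (adjusted p = 0.153). The lipid droplet gene PLIN2 fell by 1.01 ± 0.06 and ANGPTL4 by 0.86 ± 0.12, and PPARA rose by 0.49 ± 0.09. In that list 1 gene rose without vehicle replicate 1 or 2 or menthol replicate 1 or 3. Of 31 genes of focal adhesion and integrins 7 rose and 6 fell, and 7 rose and 7 fell adjusted over the list alone (adjusted p = 0.863). The integrin ITGB6 rose by 1.26 ± 0.12 and LPXN by 1.14 ± 0.07, and ITGA5 fell by 0.82 ± 0.07. Of 26 genes of DNA damage repair 4 rose and 2 fell, and 4 rose and 0 fell adjusted over the list alone (adjusted p = 0.982). The helicase gene BRIP1 rose by 0.60 ± 0.08 and the kinase gene CHEK2 fell by 0.50 ± 0.15. CHEK2 did not pass with single probesets, and no repair gene passed as lower without vehicle replicate 2 or 3 or menthol replicate 1 or 2. The genes of this list that rose numbered 2 without vehicle replicate 1 or 2 or menthol replicate 2. Those that fell numbered 1 without vehicle replicate 1 and 4 without menthol replicate 3.

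Markers of other cell types moved in both directions. Of 15 fibroblast markers 3 fell and 5 rose, and 4 fell and 6 rose adjusted over the list alone (adjusted p = 0.966). PDGFRA and FBLN1 were at -1.99 and -0.74 and TAGLN at 0.45 ± 0.09. Without vehicle replicate 1, 2 or 3 or menthol replicate 3, 3 fibroblast markers rose, and without menthol replicate 1, 2 rose. Of 11 endothelial markers 3 rose and 0 fell, as adjusted over the list alone (adjusted p = 0.0673). KDR rose by 1.42 ± 0.09 and PECAM1 by 0.60 ± 0.07. The endothelial list passed without vehicle replicate 1 (adjusted p = 0.0433) or menthol replicate 2 (adjusted p = 0.0394), in a range up to 0.173 over its camera alternatives at the preset correlation, and did not pass with an estimated correlation (adjusted p = 0.372). Of 15 leukocyte markers 2 passed, AIF1 at 0.69 ± 0.22 and CD68 at 0.29 ± 0.07, and 1 passed adjusted over the list alone (list adjusted p = 0.456); AIF1 was at 0.43 without menthol replicate 2 and did not pass without vehicle replicate 1, 2 or 3 or menthol replicate 3, under quantile or cyclic loess normalization, with single probesets, or with the replicate number as a block. CD68 did not pass without vehicle replicate 1 or 2. Of 15 androgen receptor and luminal prostate markers 3 fell and 2 rose, and 3 fell and 4 rose adjusted over the list alone (adjusted p = 0.966). HOXB13 fell by 0.77 ± 0.06 and PMEPA1 rose by 0.60 ± 0.07. Of 16 basal and stem-like markers LGR5 and ITGA6 fell and KRT15 rose by 1.54 ± 0.09. Of 14 neuroendocrine markers ENO2 and FOXA2 fell and SCG5 and NCAM1 rose, in each list as adjusted over the list alone (adjusted p = 0.966 for both lists). NCAM1 did not pass without vehicle replicate 3.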

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

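The tests over other splits of the arrays had their bounds written only after the result was seen, and the tests of probesets outside the gene analysis were chosen after the data were seen. Among the 11775 probesets with no gene named here, 104 were higher and 282 lower with menthol than with vehicle (limma, adjusted over all probesets outside the gene analysis). Among the 1388 probesets with several gene symbols, 43 were higher and 65 lower. In both sets the share past the threshold was below the 29.1% of the gene comparison. That comparison was adjusted over the genes alone, so the cutoffs on p differ and the shares cannot be compared directly. These signals lie in data that the gene comparison does not use, and no explanation was tested for them. Whether the probesets with no gene named here measure transcripts was not checked.

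The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5353 genes and the highest of the others 0 (limma; at an unadjusted p under 0.05, 7538 genes in the real split and up to 518 in the others), so 1 split of 10 gave as many genes. For genes changed at least 1.5-fold the real split gave 1032 and the highest other 0, again 1 of 10. For gene lists the real split gave 12 and the highest other 11, again 1 of 10.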

How the results depend on the processing

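Cyclic loess normalization was chosen after the data were seen; the other alternatives were planned. The number of genes past the threshold stayed within 1.5 times of 5353 under every alternative except the threshold of 0.01, which gave 2841, a stricter limit by construction; without 1 array it ranged from 3839 to 4828. The number changed at least 1.5-fold, 1032, became 659 with the stricter filter on dim genes, where fewer genes are tested, and 1666 with every probeset as its own unit, where more are; list tests were not run on single probesets. The number of gene lists, 12, became 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 25 with fry, and lay between 10 and 14 otherwise. The median SD between replicates, 0.0892, became 0.0654 with that filter, which leaves out the dim genes, whose SD is higher. The share of genes past the threshold that were higher, 50.1%, ranged from 42.85% with the stricter filter on dim genes to 55.3% with quantile normalization. Of the 170 genes past the threshold that were followed by name, 9 lost the call under at least 1 alternative and 0 changed sign among those called. Most of these were picked for large changes, so their stability does not stand for that of all calls. Of all 5353 calls, 3717 were kept without vehicle replicate 3, 3883 with every probeset as its own unit and 5260 with the mean of a gene's probesets. The values did not show that array numbers pair the samples, and they cannot exclude it. Deviations of same-numbered arrays correlated at 0.00647, -0.00721 and 0.091, and those of unlike numbers between -0.072 and 0.0721. Not every array correlated best with its own number. With the number as a replicate block, 4868 genes, 1032 genes changed at least 1.5-fold and 12 lists passed. For dim genes the signal over background limits what can be seen.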

Other observations

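The comparison of the G1/S and G2/M lists, that of the small RNA classes, their counts and medians without 1 array or under another scaling, the counts of hosts that fell and the test of neighbours with separate spans were chosen only after the result was seen, as was cyclic loess normalization. Genes and small RNAs singled out in the next paragraphs were chosen after their values were seen, except DHRS9, IFIT2, SAMD9L, SAMD9, IFIH1, CD274 and PDCD1LG2.

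RDH10, which like DHRS9 oxidises retinol, fell by 1.39 ± 0.06 (SE, n = 3 per group) on the log2 scale (limma adjusted p = 3.43e-05). The homeobox gene HOXB9 fell by 1.53 ± 0.06, the calprotectin subunit S100A8 by 1.40 ± 0.10 and the alarmin IL33 by 1.34 ± 0.12. Of 35 interferon response genes 16 rose and 6 fell, and 16 rose and 7 fell adjusted over the list alone, while the list did not pass in camera (adjusted p = 0.0673). IFIT2 rose by 1.23 ± 0.06, SAMD9L by 1.19 ± 0.14, SAMD9 by 1.03 ± 0.07 and the RNA sensor IFIH1 by 0.78 ± 0.16. Without vehicle replicate 2 or 3, 2 interferon response genes fell in place of 6, and without menthol replicate 1 or 3, 3 fell; the list passed without menthol replicate 1, with either filter on dim genes, with the trended prior and with array weights, at adjusted p from 0.00375 to 0.14 over its camera alternatives at the preset correlation, and did not pass with an estimated correlation (adjusted p = 0.697).

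Of 15 spliceosomal small nuclear RNA genes 8 rose and 0 fell, while of 192 small nucleolar and Cajal body RNA genes 12 rose and 50 fell. RNU5D-1 rose by 3.17 ± 0.42 and RNU5E-1 by 2.37 ± 0.26; these U5 genes are near-identical copies, so their separate values are uncertain. SNORD45C fell by 1.25 ± 0.15 and SNORD28 by 0.79 ± 0.08, while the Cajal body RNA SCARNA6 rose by 1.45 ± 0.09. Menthol replicate 1 stood above the other menthol arrays for RNU5D-1, at 9.80 against 7.97 and 8.21, and for RNU5E-1, at 10.04 against 9.11 and 9.12. Without it RNU5D-1 rose by 2.60 and RNU5E-1 by 2.07, and 6 small nuclear RNA genes rose and 0 fell, with a class median of 0.44 in place of 0.64. Without vehicle replicate 2, 6 small nucleolar and Cajal body RNA genes rose in place of 12. Without each array in turn the class medians lay between 0.44 and 0.71 for small nuclear RNAs and between -0.17 and -0.10 for small nucleolar and Cajal body RNAs. Under quantile normalization, equal array medians and cyclic loess normalization they lay between 0.62 and 0.64 and between -0.19 and -0.16, and under cyclic loess normalization 8 small nucleolar and Cajal body RNA genes rose and 56 fell.

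Brighter genes had lower fold changes than dimmer ones, so an intensity-dependent shift between the groups might account for the falls of lists of bright genes. Against 10000 random lists matched on expression, the median of the G2/M list lay at percentile 0 and that of glycolysis at 0.01. Ribosomal proteins lay at 0.42, ribosome biogenesis at 1.91 and cholesterol synthesis and uptake at 100. The random lists drew genes independently, while members of these lists were correlated, at an estimated 0.42 for G2/M and 0.09 for ribosome biogenesis. The percentiles are therefore too extreme and alone do not exclude the shift. The random lists had a typical median of -0.05 for G2/M and -0.03 for cholesterol synthesis and uptake, against -0.51 and 0.41. For glycolysis the typical median was -0.06, against -0.35. For the G2/M, cholesterol and glycolysis lists this argues against the shift as the whole cause. Under cyclic loess normalization the G2/M, glycolysis, ribosomal protein, ribosome biogenesis and cholesterol lists still passed in the same direction. In that order their medians went from -0.51 to -0.45, -0.35 to -0.26, -0.18 to -0.10, -0.18 to -0.12 and 0.41 to 0.46. For ribosomal proteins the camera adjusted p was 0.0234, in a range of 4.21e-07 to 0.0234 over its camera alternatives at the preset correlation. For ribosome biogenesis it was 0.0457, in a range of 8.05e-05 to 0.0457. The shift stays a candidate explanation for the 4 falls, for those of G2/M and glycolysis only in part. With an estimated correlation no list passed. Oxidative phosphorylation lay at percentile 10.44, and its median went from -0.12 to -0.05 and its adjusted p from 0.0135 to 0.417 under cyclic loess normalization (0.00486 to 0.417 over its camera alternatives at the preset correlation, and 0.583 with an estimated correlation), so for that list the shift stays a candidate explanation. Fewer cycling cells might also lower the G2/M list, and the comparison with G1/S assumes that both lists would fall by about as much, which was not shown. The G1/S median lay 0.5287 above the G2/M median, beyond the SD of 0.27 of the G1/S members. That SD is a spread between genes and not an error of the median. These values had been seen and are not an independent test. Fewer cycling cells are therefore not excluded, and a response to menthol in G2/M genes stays open as a hypothesis.

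A yield that changed alike for all small RNAs would move both classes one way, but the median of the small nuclear RNAs lay 0.7946 above that of the small nucleolar RNAs, at 0.64 against -0.15; this is the pattern itself, not an independent test, and a yield that differs between the classes was not tested. A change or signal of the host transcript might account for the falls of small nucleolar RNAs, and over 74 host genes, tested first, Spearman's rho was 0.19 (permutation p = 0.114, adjusted 0.114) and Pearson's r 0.28 (p = 0.016, adjusted 0.0321). Over the 96 pairs of small RNA and host, the unit set in the prediction beforehand but run only after those values were seen, rho was 0.23 (p = 0.0245, adjusted 0.0326) and r 0.33 (p = 0.00106, adjusted 0.00424), and r was 0.33 without the 2 pairs whose hosts lay farthest from the median. The prediction had counted a missed p as evidence against the host, which it is not, and the 4 correlations, across genes that are not independent, differ in their side of the threshold, so the part of the host cannot be told apart here. A host here is the only measured protein-coding or long non-coding gene whose span holds the small RNA, with strand and introns unchecked. Of 21 small nucleolar and Cajal body RNAs that fell and had a measured host, the host also fell for 14 and rose for 0 (11 of 17 distinct hosts fell). Of the other 75 with a measured host the host fell for 30. This difference was not tested.

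CD274 and PDCD1LG2 neighbour each other in assembly GRCh38.p14, and a hypothesis is that neighbouring genes moved together more widely. Over 15239 adjacent pairs of protein-coding genes whose symbols do not start alike, Pearson's r of the log2 fold changes was 0.1068, against at most 0.0339 in 100000 shuffled orders (one-sided permutation p = 1e-05, the smallest they can give; the correlation is across genes, which are not independent replicates). Overlapping spans or similar intensity might give such a correlation, but over 13768 pairs with separate spans and after removal of the intensity trend r was 0.1004 (p = 1e-05), above the highest shuffled value of 0.0365. The correlation is small, and no other explanation was tested.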
